A study of Homo sapiens with 2 samples.

How the data were processed

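Gene expression was measured in 769-P, an established human cell line from a clear-cell renal cell carcinoma, on Affymetrix whole-transcript arrays. 1 array held RNA of cells carrying an empty EGFP lentiviral vector, and 1 array held RNA of cells carrying the same vector with the FOXK2 coding sequence. Per the labels' protocols, total RNA was extracted with Trizol, amplified and labelled with biotin with the WT PLUS reagent kit. Per the submitters' processing notes, the authors used Affymetrix Expression Console. The algorithm, its settings, the version and the genome build are not given in the sources used here.

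The deposited values are log2 expression values, 1 per transcript cluster and array, for 67528 transcript clusters. That the authors' values are on a log2 scale was read from their range, 2.13 to 19.93 in both arrays, and is not written in the labels. The median over all transcript clusters was 4.48 in the empty vector array and 4.55 in the FOXK2 array. 33 and 30 transcript clusters, respectively, stood at the highest value, where a difference cannot be seen. In 1226 transcript clusters (1.82%) the 2 arrays held exactly the same value. Probe intensities and their background were not used here, so whether a transcript cluster lay above background is not known.

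Transcript clusters were named through the platform's annotation. 23781 had 1 gene symbol, 1543 had several and were left out, and 42204 had none. Symbols were updated with the RefSeq gene table of GRCh38.p14 by Entrez identifier (21497 transcript clusters), by current symbol (1974) or by an unambiguous older symbol (306), and 4 kept their name. Because the array's build is not named, no coordinates are given, and the table served only for names, gene types and the order of genes. The chromosome came from the transcript cluster's identifier, and 22261 of 22275 genes lay on the same chromosome in that table. Transcript clusters of a gene were averaged, which gave 22411 genes, 21883 of them with 1 transcript cluster.

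The difference of a gene is its log2 value in the FOXK2 array minus that in the empty vector array, with no further normalization. A gene entered the counts if its mean over both arrays was at or above the median of all transcript clusters with 1 gene symbol, 5.24, called the level limit below; 11263 genes passed, 9603 of them protein-coding. It was called higher or lower at a difference of at least 1 in size, which is 2-fold. With 1 array per group there is no estimate of the error, no test and no p-value, and none of the differences has a replicate check. The number of arrays limits the precision. Within an array pair, 97 genes had several transcript clusters above the level limit, and their differences disagreed by a median of 0.19 between the clusters of a gene.

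26 lists of genes were fixed before the data were examined, as were the design, the rule for named genes and most of the alternatives; 4 further groups were taken by the start of the symbol (SNORD, SNORA, MIR, RNU). 386 of the 448 listed genes were measured, each in 1 list. All measured members of a list entered its median, whatever their level. The median was placed among the medians of 10000 random lists of the same size, drawn from all genes and matched on mean expression in 20 level bins. This percentile describes these 2 arrays and is no test of the treatment; random lists also lack the co-regulation of real pathways. A list is described as standing apart where its median lay outside the middle 95% of the random lists. The named genes were FOXK2, EGFR, the 10 protein-coding genes with the largest positive and the 10 with the largest negative difference above the level limit, and 2 to 4 members of each list from the 4 above the level limit with the largest differences in size (1 for the leukocyte and endothelial list, which has only 1 there); other genes named were chosen after their values were seen.

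The alternatives were centring of the arrays on their medians, removal of a loess trend on level (span 0.3), quantile normalization, the brightest transcript cluster per gene, other level filters, other fold limits, protein-coding genes only, and random lists not matched on level. The description by chromosome, and the alternative in which the running median of 51 neighbouring genes was subtracted, were added after the data had been seen. For that description, each chromosome was divided once, at the place with the largest scaled difference in mean, with at least 20 genes on each side and differences bounded at 1 in size.

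The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6. They were tested on simulated data built from the levels and the spread of the 11263 genes: 100% of 200 genes changed 4-fold were called, and 1.03% of the unchanged genes were called. Since that spread comes from the same 2 arrays, this share tests the calculation and is no chance level for the counts. A list of 15 genes raised by 0.5 reached the percentile 99.99, and 6.5% of 200 unchanged lists fell outside the middle 95%. In 100 simulated chromosomes of 400 genes with 150 genes shifted by -0.35, the boundary was found within a median of 2 genes.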

Results

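The study compared the transcriptome of 769-P cells that overexpressed FOXK2, a forkhead transcription factor, with that of cells carrying the empty EGFP vector. 769-P is a line from a human clear-cell renal cell carcinoma, a kidney tumour of proximal tubule origin. 1 array was run per group, so every difference below is a single measurement, given as the log2 value with FOXK2 minus that with empty vector. The 2 arrays were similar over all 67528 transcript clusters (Pearson's r across transcript clusters 0.988, which are not independent replicates). Of the 11263 genes above the level limit, 95% differed by between -1.09 and 0.93, and the median difference was -0.050.

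FOXK2 itself had a log2 value of 13.82 in the FOXK2 array against 9.36 in the empty vector array, a difference of 4.46, and ranked 3 among the 11263 genes. The direction was that given by the labels. The vector carries only the coding sequence, so any probes in the untranslated parts measured the cell's own transcript. EGFR, the epidermal growth factor receptor, which was named in advance, had a log2 value of 8.43 with FOXK2 and 9.46 with empty vector, a difference of -1.03, or 2.05-fold lower. EGFR thus lay at the 2-fold limit. It was just short of it after removal of the trend on level (-0.95), after quantile normalization (-0.94) and after subtraction of the running median of its neighbours (-0.99).

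At least 2-fold differences were found in 240 genes that were higher with FOXK2 (2.13% of those above the level limit) and in 344 that were lower (3.05%). 14 genes were higher by at least 3 on the log2 scale and 7 were lower by as much. The split between higher and lower genes was not stable: after subtraction of the running median along each chromosome, 269 genes were higher and 230 lower, of which 224 and 223, respectively, were among those called from the values as deposited.

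KMO, the kynurenine hydroxylase of tryptophan breakdown, was 51.3-fold higher with FOXK2, from a value of 5.15, below the level limit, to 10.83. Its fold is uncertain, since whether 5.15 lay above background is not known. SLCO4C1, an organic anion transporter of the kidney, was 36.6-fold higher and reached 15.74. FMO1, a flavin-containing monooxygenase, was 20.7-fold higher. ALDH8A1, an aldehyde dehydrogenase, was 13.7-fold higher, and CUBN, the endocytic receptor cubilin of the proximal tubule, was 10.8-fold higher. Among signalling genes, IRS2, an adaptor of the insulin receptor, was 14.3-fold higher, RGL1, an exchange factor of Ral, was 12.8-fold higher, and MACC1, a regulator of MET expression, was 10.6-fold higher. SERPINF1, which encodes a secreted serpin that inhibits vessel growth, was 15.1-fold higher.

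GDA, guanine deaminase, was 18.3-fold lower with FOXK2, and SHISA2 was 18.2-fold lower. SLFN13, a Schlafen family nuclease, was 17.4-fold lower. DPYSL3, a cytoskeletal protein of the collapsin response family, was 14.1-fold lower, and FN1, the matrix protein fibronectin, was 13.3-fold lower. ALDH1A3, an enzyme of retinoic acid synthesis, was 9.48-fold lower, and MT2A, a metallothionein, was 8.81-fold lower. ATRNL1 was 7.785-fold lower, CAVIN2, a coat protein of caveolae, was 7.66-fold lower, and TCEAL8 was 7.23-fold lower. GDA, SLFN13, CAVIN2 and TCEAL8 had values in the FOXK2 array of 4.63, 4.12, 4.35 and 4.65, below the level limit and near those of genes of other cell types such as CD3E, a T cell gene (4.57), and VWF, an endothelial gene (4.22). Whether these values lay above background is not known. Their folds are therefore uncertain and may be understated, and the order of the lowest genes is not exact. GDA, ATRNL1 and ALDH1A3 lie on chromosomes 9, 10 and 15, whose genes were lower as a group. After subtraction of the running median of their neighbours they still stood at -3.95, -2.67 and -2.92.

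**Figure D1:**
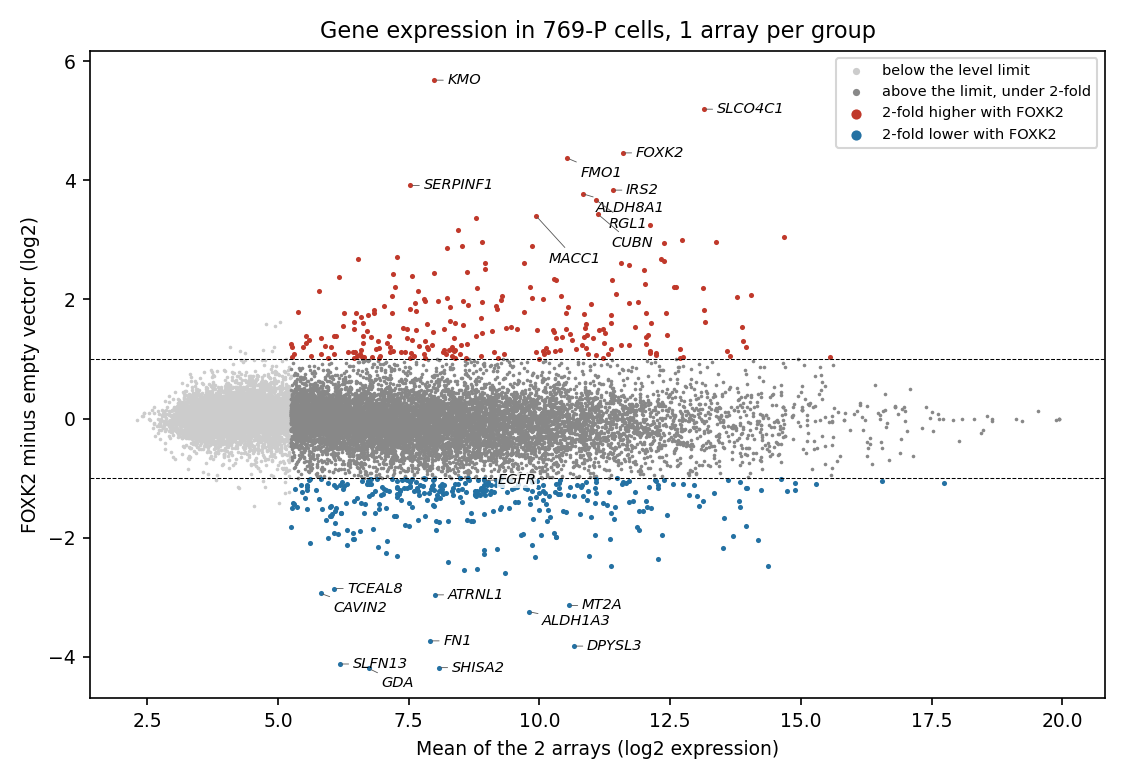
Difference between the 2 arrays (FOXK2 minus empty vector, log2, vertical axis) against the mean of both arrays (log2, horizontal axis), 1 point per gene. Red points are the 240 genes at least 2-fold higher with FOXK2 and blue points the 344 at least 2-fold lower, above a level limit of 5.24; dashed lines mark 2-fold, and FOXK2 lies at 4.46, exceeded only by KMO and SLCO4C1.

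Hypoxia-inducible genes stood furthest above zero of the lists fixed in advance. Of 15 measured, 14 had positive differences, 7 were at least 2-fold higher with FOXK2 and none was 2-fold lower. P4HA1, a collagen prolyl hydroxylase, was 4.80-fold higher, EGLN3, an oxygen-sensing prolyl hydroxylase, 4.39-fold, NDRG1 4.23-fold and ADM, the vasodilator adrenomedullin, 3.41-fold. VEGFA, the vascular growth factor, differed by 1.23, while BNIP3, a mitophagy receptor, had a difference of -0.29. The list median of 0.85 lay above those of all 10000 random lists (percentile 100). The glycolysis genes, part of which also respond to low oxygen, had a median of 0.097 over 19 genes at the percentile 92.5, and stood above the random range under 2 of 7 alternatives (percentile 98.99 after quantile normalization, 97.955 after subtraction of the running median). Among them LDHA, lactate dehydrogenase, differed by 0.96, and PFKFB3, a regulator of glycolytic flux, by -1.21.

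All 11 measured proximal tubule genes had positive differences, with a median of 0.46 at the percentile 99.98. The 2 above the level limit that were at least 2-fold higher with FOXK2 were CUBN and LRP2, the endocytic receptor megalin that acts with cubilin, which was 8.30-fold higher at 16.20 against 13.15. ANPEP, a brush border aminopeptidase, differed by 0.90, and SLC34A1, the phosphate transporter, by 0.66. Of the leukocyte and endothelial genes, which mark other cell types, only 1 of 13 lay above the level limit, the lysosomal CD68 with a difference of 0.94, and their median was 0.048 at the percentile 48.2. The epithelial list had a median of -0.056 at the percentile 23.4, and the tight junction genes CLDN1 and TJP1 were its 2 members at least 2-fold lower, by 3.92-fold and 2.89-fold.

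Replication-dependent histone genes also stood above the random lists, although only 10 of the 20 listed were measured: 9 had positive differences, none reached 2-fold, and the median was 0.36 at the percentile 99.95. H1-2, a linker histone, differed by 0.67 and H1-3, another, by 0.57. Only 5 of the 10 measured lay above the level limit, and their median was 0.44 (percentile 98.71). The 1 negative member, H1-5 at -0.84, lay below the level limit, as did the positive members H2BC13 and H2BC14, which set the list median. Near-identical histone genes can share probes, so single members are uncertain. The oxidative phosphorylation genes (median 0.17, percentile 97.52) and the forkhead genes other than FOXK2 (median 0.15, percentile 98.7) were just beyond the middle 95%, with no 2-fold member in either. UQCRC1, a subunit of respiratory complex III, stood at 0.49 but COX5A, of cytochrome oxidase, at -0.52, and among forkhead genes FOXO1 stood at 0.47, FOXL1 at 0.44 and FOXP1 at -0.41. The oxidative phosphorylation list fell back within the random range under 4 of 7 alternatives, down to the percentile 94.1, and the forkhead list under 2 of 7, down to 95.35.

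Genes of the EGFR family stood below the random lists. 9 of the 10 measured receptors and ligands had negative differences, with a median of -0.27 at the percentile 0.43. EREG, the ligand epiregulin, was 2.79-fold lower with FOXK2, at 4.63, below the level limit, so its fold is uncertain. EGFR was 2.05-fold lower, whereas ERBB3, a receptor of the family, was 2.57-fold higher. BTC, the ligand betacellulin, differed by -0.81, at 5.23 with FOXK2, just below the level limit. Of 18 output genes of the ERK pathway downstream, 13 had negative differences. IER3, DUSP5 and PHLDA1 were 2.34-fold, 2.33-fold and 2.10-fold lower, and CCND1, which encodes cyclin D1, was 4.62-fold higher. DUSP5 was just short of 2-fold after subtraction of the running median (-0.98). The list median of -0.20 lay at the percentile 3.22, within the random range, and it was -0.019 after subtraction of the running median along the chromosomes. It lay below the random range after quantile normalization (percentile 1.98) and with random lists not matched on level (0.19).

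The targets of p53 were low as well, with 12 of 14 negative and a median of -0.37 at the percentile 0.23. GDF15, a stress-induced cytokine, was 5.01-fold lower with FOXK2 and ZMAT3, an RNA-binding protein, 2.04-fold lower, though ZMAT3 was short of 2-fold after subtraction of the running median (-0.71). CDKN1A, the cell cycle inhibitor p21, had a difference of -0.39 and MDM2, the ubiquitin ligase of p53, one of -0.40. Pro-apoptotic genes had a median of -0.23 over 17 genes (percentile 3.53), and the death receptor FAS, 2.37-fold lower, was the only member to reach 2-fold, ahead of the effector caspase CASP6 at -0.88; after subtraction of the running median FAS stood at -0.88 too, short of 2-fold. Anti-apoptotic genes had a median of 0.064 over 8 genes (percentile 81.8), with BIRC2, an inhibitor of apoptosis, at 0.69 and the co-chaperone BAG3 at -0.43. Both lay within the middle 95% of the random lists matched on level, and the pro-apoptotic list lay below it with lists not matched on level (percentile 0.22).

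No listed DNA replication or mitosis gene reached 2-fold. Of 19 DNA replication genes, 14 had positive differences and the median was 0.10 (percentile 96.3), with MCM6, a subunit of the replicative helicase, at 0.88, GINS2, its accessory factor, at 0.55 and TYMS, thymidylate synthase, at -0.47. Of 19 mitosis genes, 16 had negative differences and the median was -0.20 (percentile 17.0), with CDC20, an activator of the anaphase-promoting complex, at -0.81 and CCNB2, a mitotic cyclin, at -0.69. MKI67 had a difference of -0.092. With random lists not matched on level the mitosis list lay at the percentile 0.325.

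Genes of the mesenchymal state had a median of -0.032 (percentile 13.8), and FN1 was the only one of 17 to reach 2-fold. VIM, vimentin, differed by -0.37 and ZEB1 by -0.64, and ACTA2, smooth muscle actin, by -0.84; only 7 of these 17 genes lay above the level limit. The mean of this list was -0.37, and its median over members above the level limit was also -0.37 (percentile 6.545). Matrix-degrading proteases and their inhibitors had a median of 0.058 (percentile 64.2), with ADAM10, a sheddase, at -0.75 and ADAMTS1 at -0.41; its mean, -0.044, had the other sign, as did its median over members above the level limit, -0.30. In the autophagy list, ULK2, a kinase that starts autophagy, was 3.55-fold lower. Its value with FOXK2 was 4.34, below the level limit, so its fold is uncertain. SQSTM1, an autophagy receptor, was 2.04-fold lower (-0.70 after subtraction of the running median, short of 2-fold). The median over the 20 autophagy genes was -0.13 (percentile 21.6, or 1.55 with lists not matched on level). Genes of the corepressor complexes that bind FOXK2 had a median of -0.25 (percentile 8.14, or 0.13 with lists not matched on level), with MTA2 at -0.73 and the deacetylase HDAC2 at -0.57. Targets of Wnt signalling had a median of 0.12 (percentile 92.2), with MYC at -0.88, TNFRSF19 at -0.84 and ZNRF3, an inhibitor of the pathway, at 0.57, and its median over members above the level limit was -0.20.

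The inflammatory list had a median of -0.098 at the percentile 1.29, but only 4 of its 15 genes lay above the level limit. Those 4 included NFKBIA, the inhibitor of NF-kB, at 0.53 and the transcription factor IRF1 at 0.19, and their median was 0.19, within the random range (percentile 89.63), as was the whole list with lists not matched on level (6.405). The interferon-stimulated genes, which can respond to viral vectors, had a median of -0.039 (percentile 5.17), with RIGI at -0.49, OAS1 at 0.48, OAS3 at -0.38 and IFI6 at -0.37. The only member of this list to reach 2-fold, IFI44 at -1.41, had a mean below the level limit. Over the 6 members of this list above the level limit the median was -0.35 (percentile 3.18). The unfolded protein response (median 0.078, percentile 89.8, XBP1 at 0.70 and ATF3 at -0.57) and cholesterol synthesis (median -0.026, percentile 62.9, mean 0.039, SQLE at -0.84 and INSIG1 at 0.59) lay within the random range. The 8 measured reference genes had a median of -0.21 (percentile 22.6), with ACTB at -0.45 and HPRT1 at -0.77, and none of them had a positive difference. All 13 measured ribosomal protein genes had negative differences, with a median of -0.31 at the percentile 5.53 and RPL8 and RPS23 lowest at -0.59 and -0.58. This list lay at the percentile 1.29 after subtraction of the running median and at 0.1 with lists not matched on level.

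Both groups of small nucleolar RNA genes had medians below those of the random lists. The H/ACA box group, which guides pseudouridylation, had a median of -0.31 over 64 genes, below all 10000 random lists (percentile 0), with 45 negative and 18 positive differences. 8 of them were at least 2-fold lower and 1 was higher, with SNORA24 at 2.82-fold lower and SNORA71D, SNORA71A and SNORA71C at 2.62-fold, 2.61-fold and 2.43-fold; these last 3 are similar copies that may share probes. The C/D box group, which guides ribose methylation, had a median of -0.10 over 174 genes, also at the percentile 0, with 105 negative and 65 positive differences and no 2-fold member. With members above the level limit only it was within the random range (percentile 2.6), and after subtraction of the running median the median was -0.049. SNORD116-26 and SNORD111 had its largest differences, -0.92 and -0.89. Part of it is the repeated SNORD116 cluster on chromosome 15. The 1059 microRNA genes had a median of 0.039 (percentile 66.8), and lay above the random range under 4 of 7 alternatives, with a median of 0.12 at the percentile 100 among members above the level limit. Here MIR2054 was 4.61-fold and MIR21 4.25-fold higher and MIR4668 was 3.90-fold lower, as labelled RNA of the locus rather than the mature microRNA. The 213 small nuclear RNA genes had a median of 0.039 (percentile 88.5, or 99.73 above the level limit only) and a mean of -0.018, with RNU6-26P 2.37-fold lower (-0.76 after subtraction of the running median, short of 2-fold) and RNU4ATAC, of the minor spliceosome, 2.11-fold lower.

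**Figure D2:**
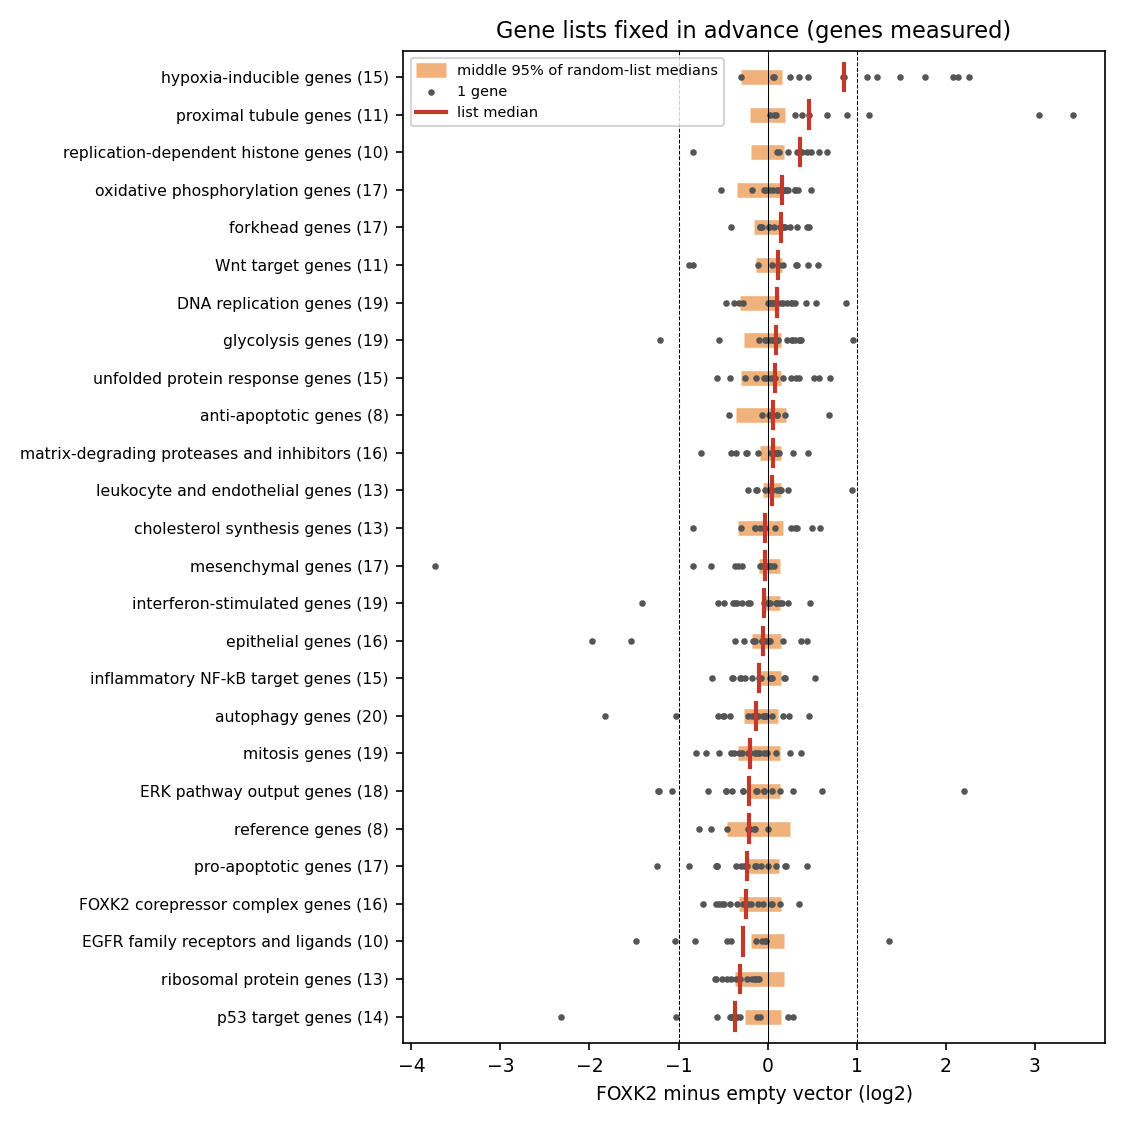
Differences (FOXK2 minus empty vector, log2, horizontal axis) of the measured genes of the 26 lists fixed in advance, 1 point per gene, with the number measured in brackets. Red bars are list medians and orange bars hold the middle 95% of the medians of 10000 random lists matched on level; the medians of the hypoxia-inducible (0.85) and proximal tubule genes (0.46) lie to the right of them, and those of the p53 targets (-0.37) and the EGFR family (-0.27) to the left.

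Along the genome, the differences were not evenly spread. Chromosome 18 had a median difference of -0.36 over 166 genes above the level limit, chromosome 15 one of -0.30 over 396, chromosome 9 one of -0.26 over 479 and chromosome 10 one of -0.24 over 437. In 1000 shuffles of the genes across the 23 chromosomes, no chromosome median fell below -0.17 or rose above 0.084. On these 4 chromosomes 75.1% of the genes had negative differences, against 52.7% on the other chromosomes. They held 13.2% of the genes, 28.6% of those at least 2-fold lower and 9.17% of those at least 2-fold higher. This description was added after the data had been seen, and the 4 chromosomes were picked for their low medians.

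Other chromosomes were divided. On chromosome 3, the median was 0.17 over the 241 genes up to SELENOK and -0.36 over the 412 genes from CCDC66 on. On chromosome 4 it was 0.16 over the 264 genes up to RPL34 and -0.43 over the 161 genes from SEC24B on. On chromosome 5 it was 0.0092 up to EGR1 and -0.29 over the 182 genes from ETF1 on. The first 64 genes of chromosome 19, up to NFIC, had a median of -0.40, with 92.2% of them negative, and the first 43 genes of chromosome 20, up to MCM8, one of -0.34. These 5 divisions were larger than any in 100 shuffles of the genes. FOXK2 and EGFR lie on chromosomes 17 and 7, whose medians were -0.018 and 0.026.

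**Figure D3:**
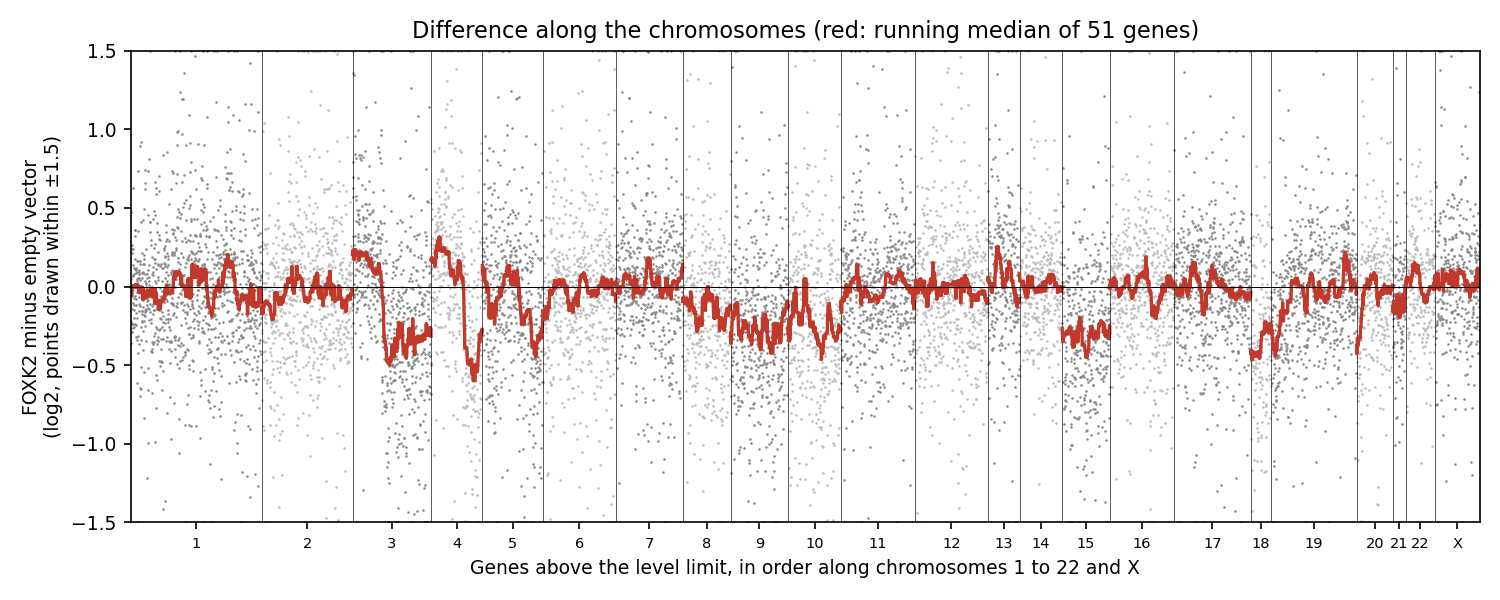
Difference between the 2 arrays (FOXK2 minus empty vector, log2, vertical axis, points drawn within 1.5 in size) for genes above the level limit in order along chromosomes 1 to 22 and X (horizontal axis). The red line is the running median of 51 genes, which spans -0.60 to 0.31; it lies below zero along chromosomes 9, 15 and 18 and changes level within chromosomes 3 and 4.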

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

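The tests with chromosomes, running medians, deletion-prone and HLA genes, and the use of the loess and glycolysis values as tests, were chosen after the patterns had been seen; the bounds for the transcript clusters without a symbol were written before their values by chromosome were known. The explanations are hypotheses about 1 array per group.

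Signal was also seen in transcript clusters that the comparisons left out because the annotation gives them no gene symbol. Of 11228 such transcript clusters on the numbered chromosomes and X above the level limit, 291 were at least 2-fold higher than in the empty vector array and 332 were 2-fold lower. The largest positive difference, 6.60, belonged to TC02004392.hg.1, at 4.85 with empty vector and 11.45 with FOXK2, and exceeded that of every named gene above the level limit.

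The genes of chromosomes 9, 10, 15 and 18 were lower together in the FOXK2 array. A trend of the difference with level does not account for the whole pattern: their median was -0.29 before its removal and -0.22 after. The lowest of 1000 shuffles gave -0.032, but these shuffles kept the same chromosomes and did not repeat the picking. A difference in DNA copy number between the 2 cell populations, such as expansion of different subclones of an aneuploid line, was tested on the transcript clusters without a symbol, since the named genes had served to pick the chromosomes. The median of 1829 such transcript clusters on these chromosomes minus that on the others was -0.055. This was below the lowest of 1000 shuffles (-0.034) but short of the -0.1 set beforehand as support. The named genes there had medians of -0.38 among the brighter and -0.19 among the dimmer. The bound made no allowance for level. The other chromosomes also included the low parts of chromosomes 3, 4, 5, 19 and 20. For both reasons the test could miss a shift. Copy number stays open, and no DNA was measured. Base composition stays open because it was not measured, although chromosomes 4 and 13, known as AT-rich like 18, were not low as a whole (0.013 and 0.048). A response of each gene to FOXK2 itself cannot be told apart from a difference between subclones with 1 array per group.

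The proximal tubule list had a high median with FOXK2, although only 3 of its 11 genes were at least 2-fold higher, 2 of them above the level limit. The list median was 0.55 after removal of the trend on level and 0.52 after subtraction of the running median, both at the percentile 100. The first is a weak check, since the random lists were already matched on level. The second changed only genes above the level limit, 7 of the 11, so it leaves a shift of the others unchecked. Cells of another person under the FOXK2 label stay open: among 8 genes that are often deleted in people or belong to the HLA family, the largest difference was 0.33 in size, which another person with the same genes would give too. An effect of FOXK2 and a difference between subclones also stay open, untested.

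The hypoxia-inducible list had a high median with FOXK2 too, with 7 of 15 genes at least 2-fold higher. The list median was 0.94 after removal of the trend on level and 1.15 after subtraction of the running median. The first is again a weak check because of the matching on level. The running median nowhere exceeded 0.31, so a shift of that size could not give the list median of 0.85. Cell density or oxygen in a single flask may have differed. The glycolysis list, part of which responds to low oxygen, need not follow as a whole, so it cannot decide this. Its median was 0.097, within the random range. It was 0.18 at the percentile 97.955 after subtraction of the running median and 0.22 at the percentile 98.99 after quantile normalization. A difference between flasks therefore stays open. An effect of FOXK2 stays open too.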

How the results depend on the processing

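No paired analysis was possible because each group has 1 array and the groups share only 1 replicate number; for the same reason no array could be left out. The counts of 240 higher and 344 lower genes depended most on the limit, as its construction implies: 686 and 1197 genes at 1.5-fold, and 98 and 83 at 3-fold, where the order of the 2 turned. With the level filter at the 75th percentile 162 genes were higher and 227 lower. Centring, loess, quantile normalization, the brightest transcript cluster, the running median and the other filters, including protein-coding genes only, moved the counts by less than 1.5 times. They gave between 222 and 288 higher and between 230 and 380 lower. No scaling moved the median of all genes by over 0.1. FOXK2 kept its direction in 5 alternatives (4.42 to 4.55), and EGFR did too (-1.07 to -0.94). Lists called apart from random lists kept that in all 7 alternatives for the hypoxia-inducible, proximal tubule, histone, EGFR family, p53 and H/ACA box genes. Centring shifts all genes alike, so it could not change a percentile and is no check of these calls. The running median was subtracted only from genes above the level limit. It left the medians of the EGFR family and histone lists, which rest on genes below that limit, unchanged. Medians of the lists standing apart moved with members above the level limit only (EGFR family -0.45, hypoxia-inducible 0.99, proximal tubule 0.66, C/D box -0.14 at the percentile 2.6, H/ACA box -0.39, and the inflammatory genes, which reversed to 0.19 as 11 of 15 members left), with the brightest transcript cluster (EGFR family -0.43), with quantile normalization (proximal tubule 0.57, H/ACA box -0.25), with centring (C/D box -0.14), with loess (C/D box -0.13) and with the running median (hypoxia-inducible 1.15, C/D box -0.049). The cause of these other moves was not tested. Signal over background is not known, so differences of genes near the level limit are likely understated: below it, 95% of genes differed by between -0.40 and 0.47.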

Other observations

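5 further gene groups were put together after values of some of their members had been seen, so their percentiles among random lists describe these arrays and are not independent evidence. Targets of NRF2, the regulator of the oxidative stress response, had negative differences in 14 of 15 genes, and 5 were at least 2-fold lower with FOXK2. Their median was -0.88, below all 10000 random lists, and -0.77 after subtraction of the running median along the chromosomes. SLC7A11, the cystine transporter, differed by -2.15, AKR1C2, an aldo-keto reductase, by -1.99, ME1, malic enzyme, by -1.41 and NQO1, a quinone reductase, by -0.95, while HMOX1, heme oxygenase, stood at 0.79. SQSTM1 was also in the autophagy list, and its difference of -1.03 was -0.70 after that subtraction. Integrin subunit genes above the level limit had negative differences in 10 of 12 cases. Of these 12 genes, 4 were at least 2-fold lower and 1 was higher, with ITGB5 at -1.52, ITGAV at -1.47 and ITGA3 at -1.40, against ITGB8 at 2.03. Over all 26 integrin genes, most of them below the level limit, the median was 0.040 at the percentile 58.6. Targets of YAP had a median of -0.30 over 24 genes at the percentile 0.04. Of the 19 above the level limit, 16 had negative differences but only 2 were at least 2-fold lower. These were NUAK2 at -1.59 and AXL, a receptor tyrosine kinase, at -1.57.

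Further kidney metabolic and brush border genes had a median of 1.32 over 18 genes at the percentile 100, and 9 of them were at least 2-fold higher. Among these 9 were SLCO4C1 and FMO1, already named with the highest genes. DPP4 and CLTRN, proteins of the brush border, stood at 14.22 and 14.87 with FOXK2 against 11.22 and 11.90 with empty vector, FABP1, the fatty acid binding protein of liver and tubule, differed by 2.68 and MME, neprilysin, by 1.94, whereas the phosphate transporter family genes SLC17A3 and SLC17A1 stood at -0.63 and -0.50. In the kynurenine pathway, KMO at 5.68 was joined by ACMSD at 2.06. AADAT, an aminotransferase, differed by -0.89, with a value of 5.15 with FOXK2, below the level limit. The median over 10 genes was 0.27 at the percentile 99.7.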
